A study of Arabidopsis thaliana and Fusarium oxysporum with 29 samples.

How the data were processed

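RNA was sequenced from roots of Arabidopsis thaliana that had been inoculated with 1 of 2 strains of the soil fungus Fusarium oxysporum, Fo5176 or Fo47, or treated with water, and from mycelium of each strain grown without a plant. Fo5176 is known as a strain that causes wilt disease in Arabidopsis, and Fo47 as a strain that lives in roots without causing disease. Per the labels' protocols, seedlings 14 days old had their roots dipped for 30 seconds in spores or water and were then kept at 28 °C with 14 h of light and 10 h of dark. Roots were taken 12, 24, 48 and 96 h after inoculation, and mycelium after 3 days of culture. The water control was taken at 12 h alone. RNA was extracted with Trizol and libraries were made with a TruSeq mRNA kit, per the labels. The extraction text also speaks of basil leaves, which none of the 29 samples is, so that passage was read as belonging to another study.

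The deposited values are FPKM, fragments scaled by transcript length and by mapped fragments, per the file headers and the sample columns, in 3 tables, for Arabidopsis, Fo5176 and Fo47 genes. Which mapped fragments enter that scaling in each table is not given in the sources used here. The submitters' processing notes name Trimmomatic 0.32, TopHat, Bowtie, Cufflinks, Cuffdiff and the build TAIR10. Columns were matched to samples by their names. The culture columns show the strain but not which sample, so the 2 culture libraries of a strain carry no replicate number and are called a and b. The number of columns of sample values left out was 0.

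The Arabidopsis table held 423066 lines, of which 6 repeated the header and 1 was incomplete. In it the water libraries and the inoculated libraries had been listed differently. Each of the first 2 water libraries listed 33849 loci once, zeros included, and the third 28883, whereas the inoculated libraries listed between 13962 and 16696 lines with no zeros, and 737 to 3309 loci stood there on several lines. Loci with 2 or more RefSeq transcripts were mostly never listed in an inoculated library (63.8% of the 2740 such loci with at least 20 FPKM in water, against 1.97% of 3653 loci with 1 transcript). A locus absent from a library, or present on several lines, was therefore treated as missing there, not as 0. PR1, PDF1.2A, JAZ10, FER1 and RFO1 were never listed in inoculated roots and have no comparison. In 7 inoculated libraries the listing stopped part of the way along chromosome 5. In the Fo5176 and Fo47 tables, respectively, 4 and 1 damaged lines were left out. Gene names and biotypes came from the RefSeq table of assembly TAIR10.1, which matched 31389 of the 33979 loci. That assembly is not the build named by the submitters, so no coordinates are printed.

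Values were transformed to log2(FPKM + 1), so a fold change is on that scale and understates the change of genes with low values. Genes with at least 1 FPKM in at least 2 libraries were tested where each group had at least 2 values. A limma fit with a mean-variance trend was made over all 25 root libraries for Arabidopsis, and over the 13 libraries of each strain for fungal genes. Contrasts compared each strain and hour with water, the strains with each other at each hour and over the mean of the 4 hours, 96 h with 12 h within a strain, and fungal genes in roots with those in culture. An F test asked whether the strain difference changed with time. Benjamini-Hochberg adjustment was made per comparison, and a gene was called at an adjusted p below 0.05. Every adjusted p of a gene is from limma. Because water was sampled at 12 h alone, comparisons with water after 12 h hold time as well as inoculation.

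The design, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The rule took the 3 largest increases and decreases per comparison among called genes. These needed a mean of at least 5 FPKM in the higher group and no overlap of libraries. For each list that camera called at the preset correlation given below, the rule took up to 4 members with the lowest adjusted p, called or not. Added to these were 14 genes named whatever their result, and 2 fungal genes each way per strain. The lists covered salicylic acid, jasmonate, ethylene, pattern-triggered immunity, camalexin, glucosinolates, antifungal proteins, oxidative stress, phenylpropanoids, suberin, nitrogen, iron deficiency, iron storage, phosphate, abscisic acid, heat shock, hypoxia, auxin, cell cycle, ribosomal proteins, expansins, sugar transport, senescence, host loci known from Fusarium interactions, morning and evening clock genes, reference genes, and cell type markers of shoot (photosynthesis), root hair and xylem. Each list was tested with limma's camera against all tested genes at a preset correlation of 0.01, and again with an estimated correlation. Adjustment was made over the lists within each comparison, not across comparisons. Of 130 list calls at the preset correlation, 7 held with an estimated one. These were jasmonate, salicylic acid and oxidative stress in Fo47 roots at 48 h, xylem in Fo5176 roots at 12 h, nitrogen between the strains at 96 h, and oxidative stress between the strains at 24 h and over the mean.

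Alternatives were other pseudocounts and filters, median-ratio scaling, quantile normalization, fits without a trend or on the compared groups alone, array weights, the replicate number as a block, a 2-fold minimum, each library left out in turn, and fry for lists. Others were chosen after seeing the data, as the closing section states. Tested on simulated data with known changes, the fit recovered 41.8% of log2 changes of 1 and 92.4% of log2 changes of 2 for Fo5176 at 48 h against water (12904 genes), and 8.96% of log2 changes of 2 and 57.6% of log2 changes of 4 for Fo5176 fungal genes at 48 h against culture (15267 genes). Depth was not given. For the fungal tables it was derived from the steps between low values of a gene, since 59.4% to 91.4% of low values lay on whole steps, and it is known up to a small whole factor. The same steps held for 19.1% to 28.8% of low plant values in inoculated libraries, so no plant depth was derived there. Tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.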

Results

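Transcript levels were measured in 25 root libraries and 4 culture libraries. The roots comprised 3 water libraries at 12 h, 3, 2, 3 and 3 Fo5176 libraries at 12, 24, 48 and 96 h, and 2, 3, 3 and 3 Fo47 libraries at the same hours, and there were 2 culture libraries of each strain. The labels do not say that replicates came from separate plants or cultures, so p-values measure only the spread between these samples. Over 3706 loci listed in all root libraries, the first 2 principal components held 40.4% and 21.1% of the variance, and the first placed water and 96 h at the end opposite to 12 h and 24 h. The shoot marker index is a relative log2 score of 16 photosynthesis genes, centred over the root libraries. It was -2.54 to -1.96 in water, and at 12 h 1.03 to 4.22 (Fo5176) and 2.85 to 3.06 (Fo47). At 96 h it was -2.16 to 0.142 in both. FPKM sums per inoculated library lay between 755394 and 5273593, except in Fo5176 12 h replicate 1 with 24686639, where 69 lines held 100000 FPKM or more. By the steps between low values, 1 fragment was worth 0.979 and 2.01 times as much in water replicates 2 and 3 as in replicate 1. The plant depth of the inoculated libraries is unknown. A value given below for a gene in a comparison is its log2 fold change. List counts are of the members measured, and camera values are given at the preset and at an estimated correlation. A list said to rank above or below other genes did so at the preset correlation, which most did not keep at an estimated one. Where rescaling changed the main count of a list by over 1.5 times, brackets opening with scaled give it after median-ratio scaling and quantile normalization.

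**Figure D1:**
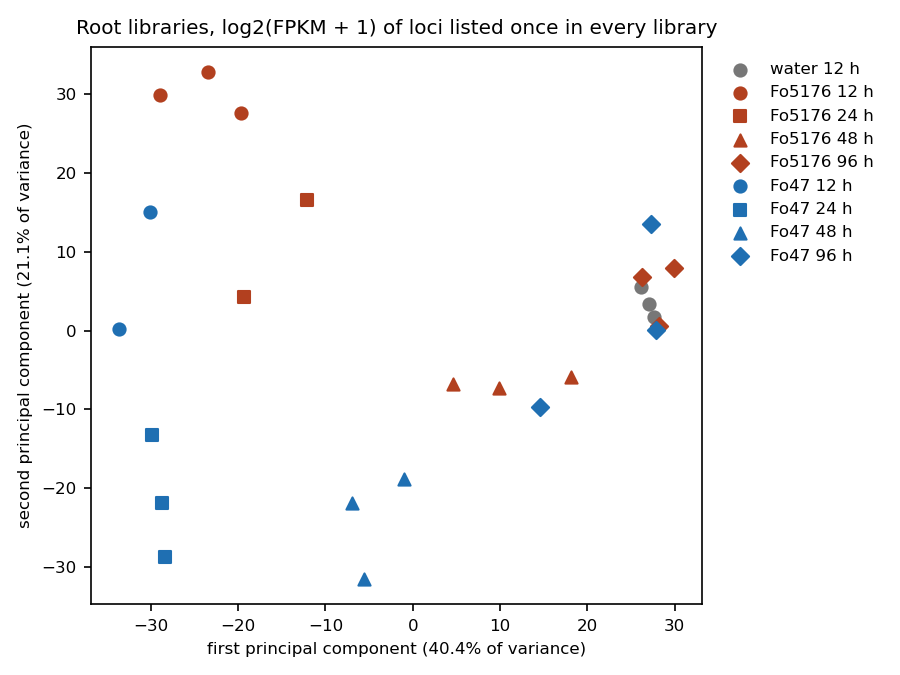
Scores of the 25 root libraries on the first 2 principal components of log2(FPKM + 1) over 3706 loci, coloured by treatment and shaped by hour. On the first component, with 40.4% of the variance, water lies at 26.1 to 27.7, 96 h at 14.6 to 30.0 and 12 h at -33.7 to -19.6.

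In roots 12 h after Fo5176, the antifungal and indole defence lists ranked above other genes, and the jasmonate, suberin, xylem and root hair lists below them, of which only xylem, with 2 members, kept its call at an estimated correlation. OSM34, an osmotin-like protein, stood at 56.5 ± 5.55 FPKM (SD, n = 3) in water and 434 ± 12.2 (SD, n = 3) with Fo5176, a change of 2.92 (SE 0.43, adjusted p = 4.82e-05). CYP71A12, which acts in camalexin synthesis, changed by 3.71 (SE 0.29, adjusted p = 3.77e-08), and CYP82C2, an indole cyanogenic pathway enzyme, by 5.72 (SE 0.45, adjusted p = 1.43e-07). TAT3, a jasmonate-responsive tyrosine aminotransferase, fell from 517 ± 62.2 FPKM (SD, n = 3) to 3.63 ± 2.43 (SD, n = 3), -6.92 (SE 0.36, adjusted p = 1.72e-09), and XCP2, a protease of developing xylem, from 147 ± 1.3 FPKM (SD, n = 3) to 9.07 ± 4.1 (SD, n = 3), -3.95 (SE 0.31, adjusted p = 3.55e-08). Among antifungal proteins 8 of 10 members rose (8 adjusted over the list alone), with PLA2A, a patatin-like lipase, at 3.22 (SE 0.43). Their median was 2.35 (camera adjusted p = 0.00602 preset and 0.241 estimated). For tryptophan and camalexin synthesis 10 of 15 members rose and 1 fell (10 and 1 adjusted over the list alone). Their median was 1.12 (camera adjusted p = 0.0461 preset and 0.561 estimated). In the ethylene list 12 of 21 members rose (13 adjusted over the list alone), with PR3, a basic chitinase, at 2.85 (SE 0.31). Its median was 0.986 (camera adjusted p = 0.0377 preset and 0.561 estimated). Of the jasmonate genes 1 of 18 members rose and 9 fell (1 and 9 adjusted over the list alone), among them the biosynthetic enzyme AOS at -1.83 (SE 0.31) and the repressor JAZ2 at -1.23 (SE 0.27). Their median was -1.03 (camera adjusted p = 4.33e-06 preset and 0.238 estimated). Of the salicylic acid genes 2 of 13 members rose and 5 fell (2 and 5 adjusted over the list alone), with the transporter EDS5 at -2.17 (SE 0.38). Their median was -0.51 (camera adjusted p = 0.00125 preset and 0.238 estimated). Some nitrogen uptake genes rose, NRT2.1 by 1.93 (SE 0.39, adjusted p = 0.000796) and 8 of 17 in the list (scaled 5 and 6), which camera did not call (adjusted p = 0.174). In the suberin list 1 of 16 members rose and 8 fell (1 and 9 adjusted over the list alone). Their median was -0.811 (camera adjusted p = 5.32e-06 preset and 0.238 estimated). For root hairs 5 of 6 members fell (5 adjusted over the list alone, median -1.86, camera adjusted p = 9.61e-06 preset and 0.238 estimated), with the peroxidase PRX44 at -3.32 (SE 0.42), and for xylem 2 of 2 members fell (2 adjusted over the list alone, median -3.55, camera adjusted p = 3.17e-05 preset and 0.0431 estimated). In the cell cycle list 6 of 11 members fell (8 adjusted over the list alone, median -1.02, camera adjusted p = 7.99e-06 preset and 0.238 estimated), with KN, a syntaxin of dividing cells, at -2.28 (SE 0.31), and in the heat shock list 6 of 16 members fell (6 adjusted over the list alone, median -1.65, camera adjusted p = 2.79e-05 preset and 0.559 estimated), with the factor HSFA7A at -3.91 (SE 0.41). Shoot markers were high in the same libraries. Among photosynthesis genes 24 of 24 members rose (24 adjusted over the list alone), with the antenna protein LHCB2.1 at 0.549 ± 0.119 FPKM (SD, n = 3) in water and 172 ± 164 (SD, n = 3). Their median was 4.76 (camera adjusted p = 4.33e-06 preset and 0.559 estimated). The largest decreases after TAT3 were FAMT, a methyltransferase, at -6.12 (SE 0.36) and AT5G19110 at -6.02 (SE 0.37), and the largest increase was the pseudogene AT4G06477 at 10.38 (SE 1.86), which was not called with unlisted loci at 0. In all, 4822 of 10674 genes were called, 3803 of them higher, and the median gene stood at 0.398. Calls were higher in 78.9% of cases, against 57.5% after median-ratio scaling and 60.4% after quantile normalization. With the shoot marker covariate 847 were called. The index lies apart between water and this group, so the covariate by itself widens the errors of the comparison. Counts with it, here and below, are not a share due to shoot tissue.

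At 24 h after Fo5176, the antifungal and photosynthesis lists again ranked above other genes, and the heat shock, suberin and jasmonate lists below them. OSM34 reached 842 ± 129 FPKM (SD, n = 2), 3.87 (SE 0.48, adjusted p = 1.95e-05) against water, and PRX34, a root peroxidase, changed by 2.61 (SE 0.28, adjusted p = 3.25e-06). CYP71B15, the last enzyme of camalexin synthesis, changed by 3.34 (SE 0.32, adjusted p = 5.95e-06). HSP70, a chaperone, fell from 2120 ± 337 FPKM (SD, n = 3) to 84.5 ± 7.41 (SD, n = 2), -4.62 (SE 0.73, adjusted p = 0.000201), and AGP30, a root arabinogalactan protein, changed by -4.72 (SE 0.58, adjusted p = 4.15e-05). In the antifungal list 7 of 10 members rose (7 adjusted over the list alone). Its median was 2.4 (camera adjusted p = 0.00136 preset and 0.295 estimated). In the heat shock list 4 of 6 members fell (6 adjusted over the list alone). Its median was -3.9 (camera adjusted p = 2.65e-05 preset and 0.295 estimated). Of the suberin genes 7 of 12 members fell (7 adjusted over the list alone). Their median was -0.995 (camera adjusted p = 0.00031 preset and 0.295 estimated). In the jasmonate list 1 of 17 members rose and 6 fell (1 and 7 adjusted over the list alone), with TAT3 at -2.81 (SE 0.41). Its median was -0.612 (camera adjusted p = 0.000815 preset and 0.521 estimated). Of the salicylic acid genes 5 of 13 members fell (5 adjusted over the list alone), with FMO1, a monooxygenase of systemic resistance, at -2.76 (SE 0.5). Their median was -1.02 (camera adjusted p = 0.00078 preset and 0.295 estimated). For abscisic acid 1 of 8 members rose and 4 fell (1 and 4 adjusted over the list alone), with the dehydrin COR47 at -1.62 (SE 0.32). Their median was -0.876 (camera adjusted p = 0.0359 preset and 0.563 estimated). Of the cytosolic ribosomal proteins 5 of 6 members rose (5 adjusted over the list alone) (scaled 2 and 2), with RPL24A at 1.25 (SE 0.23). Their median was 0.857 (camera adjusted p = 0.0441 preset and 0.563 estimated). All 19 measured photosynthesis genes rose, with PSAD1, a photosystem I subunit, at 5.23 (SE 0.93) (median 4.8, camera adjusted p = 2.78e-05 preset and 0.563 estimated). The largest increases included AT4G06477 at 11.28 (SE 1.86), AT5G09700 at 7.97 (SE 0.4) and AT7SL-1, a signal recognition particle RNA, at 6.5 (SE 0.54). Of 7866 genes 3012 were called, 2404 higher, with a median of 0.395. Of these calls, 79.8% were higher, 52.1% after median-ratio scaling and 50.8% after quantile normalization, and the count was 1882 without Fo5176 24 h replicate 3. With the shoot marker covariate 603 were called.

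At 48 h after Fo5176, the iron deficiency list ranked above other genes and the jasmonate and suberin lists below them. BHLH39, a transcription factor of the iron deficiency response, averaged 1.16 ± 0.391 FPKM (SD, n = 3) in water and changed by 3.28 (SE 0.4, adjusted p = 0.000107), and ABCG37, an exporter of coumarins, changed by 2.05 (SE 0.31, adjusted p = 0.00083). GolS7, a galactinol synthase, rose from 0.129 ± 0.0446 FPKM (SD, n = 3) to 114 ± 144 (SD, n = 3), 5.8 (SE 0.81, adjusted p = 0.00408). AT2G41640, annotated as a glycosyltransferase family protein, fell to 8.06 ± 1.6 FPKM (SD, n = 3), -3.83 (SE 0.26, adjusted p = 9.17e-08). In the iron deficiency list 8 of 17 members rose (12 adjusted over the list alone) (scaled 7 and 2). Its median was 1.62 (camera adjusted p = 0.000326 preset and 0.254 estimated). In the jasmonate list 3 of 17 members fell (3 adjusted over the list alone). Its median was -0.689 (camera adjusted p = 7.12e-11 preset and 0.102 estimated). In the suberin list 2 of 18 members rose and 5 fell (2 and 5 adjusted over the list alone), with the acyltransferase GPAT7 at -1.65 (SE 0.31). Its median was -0.264 (camera adjusted p = 4.23e-08 preset and 0.102 estimated). Salicylic acid genes were low as a list, as 1 of 15 members fell (1 adjusted over the list alone), the member being DLO1, which breaks salicylic acid down, at -1.48 (SE 0.33). Their median was -0.336 (camera adjusted p = 3.72e-05 preset and 0.102 estimated). For pattern-triggered immunity 1 of 21 members rose and 1 fell (1 and 1 adjusted over the list alone). Their median was -0.0563 (camera adjusted p = 0.000243 preset and 0.578 estimated). The largest decreases after AT2G41640 were AT4G08170 at -3.26 (SE 0.65) and AT1G32910 at -2.92 (SE 0.34), and the largest increases, not called with unlisted loci at 0, were AT4G06477 at 11.21 (SE 1.86) and the pseudogene AT1G80800 at 8.17 (SE 0.4). The shoot marker index was -1.98 in 1 library and -0.819 and -0.749, above all water libraries, in the others. Of 12904 genes 2081 were called, 1886 higher, with a median of 0.369. Calls were higher in 90.6% of cases, 64% after median-ratio scaling and 49.1% after quantile normalization, and single libraries moved the count to 694 without water replicate 1, 848 without water replicate 3, 1222 without Fo5176 48 h replicate 1 and 632 without Fo5176 48 h replicate 3. With the shoot marker covariate 1319 were called.

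At 96 h after Fo5176, the nitrogen, hypoxia, suberin and phenylpropanoid lists ranked below other genes and the antifungal list above them, by some of their members. NRT2.1, a high-affinity nitrate transporter, fell from 142 ± 18 FPKM (SD, n = 3) to 20.5 ± 3.56 (SD, n = 3), -2.74 (SE 0.39, adjusted p = 0.000297), and NPF7.3, which loads nitrate into the xylem, to 16.4 ± 8.84 (SD, n = 2), -2.11 (SE 0.35, adjusted p = 0.00128). PDC1, a pyruvate decarboxylase of fermentation, fell from 68.5 ± 1.34 FPKM (SD, n = 3) to 10.8 ± 2.03 (SD, n = 3), -2.57 (SE 0.44, adjusted p = 0.00141). TAT3 rose to 1980 ± 493 FPKM (SD, n = 3), 1.91 (SE 0.36, adjusted p = 0.00348), in contrast to its decrease at 12 h. GolS7 rose to 201 ± 78.8 FPKM (SD, n = 3), 7.39 (SE 0.81, adjusted p = 0.00112). In the nitrogen list 6 of 16 members fell (6 adjusted over the list alone). Its median was -0.582 (camera adjusted p = 1.05e-05 preset and 0.121 estimated). In the hypoxia list 2 of 13 members fell (4 adjusted over the list alone) (scaled 5 and 4). Its median was -0.785 (camera adjusted p = 3.97e-06 preset and 0.25 estimated). For phenylpropanoids 1 of 14 members rose and 3 fell (2 and 5 adjusted over the list alone), with LAC11, a laccase of lignification, at -1.44 (SE 0.23) and FAH1, a hydroxylase of lignin monomers, at 2.69 (SE 0.53). Their median was -0.556 (camera adjusted p = 2.09e-05 preset and 0.211 estimated). For suberin 4 of 18 members fell (9 adjusted over the list alone) (scaled 7 and 7). Their median was -0.459 (camera adjusted p = 0.000373 preset and 0.546 estimated). In the antifungal list 4 of 11 members rose (5 adjusted over the list alone). Its median was 0.866 (camera adjusted p = 0.0328 preset and 0.577 estimated). The largest changes included AT5G28520 at 6.64 (SE 0.98), AT2G41640 at -3.87 (SE 0.26) and AT5G52390 at -2.87 (SE 0.5). Of 11967 genes 1017 were called, 783 higher, with a median of 0.17. Of these calls, 77% were higher, 57.2% after median-ratio scaling and 50.8% after quantile normalization, and single libraries moved the count to 489 without water replicate 1, 568 without water replicate 2, 530 without water replicate 3, 506 without Fo5176 96 h replicate 1 and 565 without Fo5176 96 h replicate 2. With the shoot marker covariate 663 were called.

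**Figure D2:**
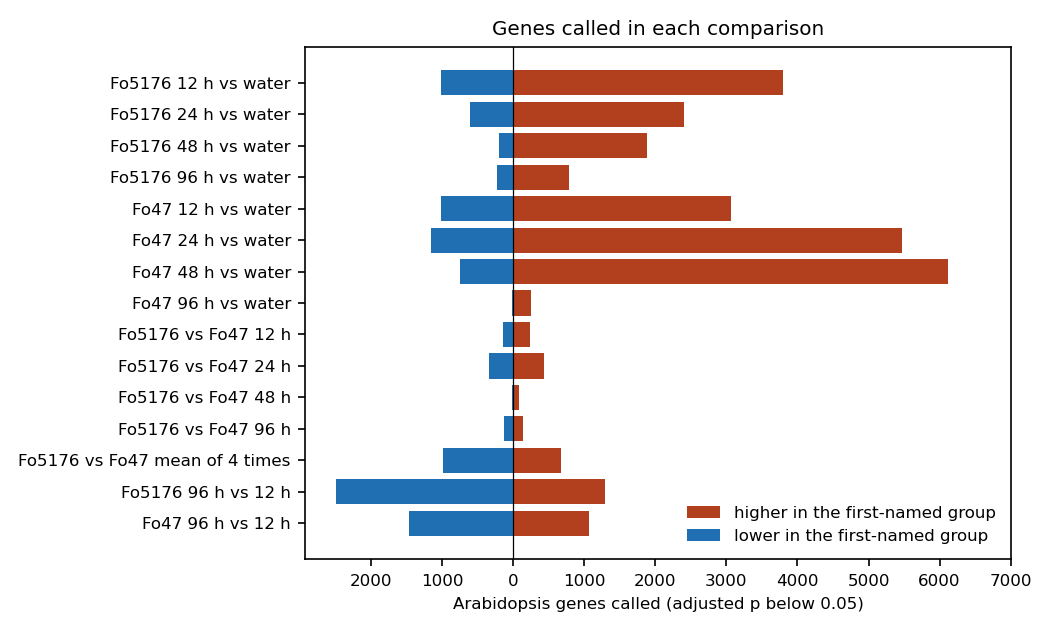
Number of genes called (adjusted p below 0.05, limma) per comparison, with bars for genes higher and lower in the first-named group. Against water the number with Fo5176 is 4822 at 12 h and 1017 at 96 h, and with Fo47 it is 6866 at 48 h and 272 at 96 h.

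In roots 12 h after Fo47, the strain without disease, the nitrogen and antifungal lists ranked above other genes and the jasmonate, heat shock and xylem lists below them. NRT2.1 rose to 1930 ± 262 FPKM (SD, n = 2), 3.76 (SE 0.44, adjusted p = 6.61e-06), and the ammonium transporters AMT1;3 and AMT1;2 changed by 3.64 (SE 0.41, adjusted p = 4.17e-06) and 3.08 (SE 0.36, adjusted p = 6.11e-06). OSM34 changed by 2.65 (SE 0.48, adjusted p = 0.000377) and CHIA, an acidic chitinase, by 1.88 (SE 0.24, adjusted p = 1.57e-05). JAZ2 fell from 553 ± 45.1 FPKM (SD, n = 3) to 113 ± 4.9 (SD, n = 2), -2.27 (SE 0.3, adjusted p = 2.39e-05). In the nitrogen list 12 of 17 members rose (13 adjusted over the list alone). Its median was 1.18 (camera adjusted p = 0.000614 preset and 0.17 estimated). In the antifungal list 8 of 9 members rose and 1 fell (8 and 1 adjusted over the list alone) (scaled 5 and 5). Its median was 1.48 (camera adjusted p = 0.0424 preset and 0.387 estimated). In the jasmonate list 1 of 12 members rose and 10 fell (1 and 10 adjusted over the list alone, median -2.16, camera adjusted p = 2.86e-08 preset and 0.17 estimated), and in the salicylic acid list 1 of 8 members rose and 6 fell (1 and 6 adjusted over the list alone, median -1.14, camera adjusted p = 0.00258 preset and 0.17 estimated). For pattern-triggered immunity 1 of 21 members rose and 6 fell (1 and 5 adjusted over the list alone), although FRK1, a receptor kinase induced by bacterial flagellin, changed by 2.74 (SE 0.34). Their median was -0.423 (camera adjusted p = 0.000614 preset and 0.387 estimated). In the heat shock list 6 of 12 members fell (6 adjusted over the list alone), with HSFA7A at -4.01 (SE 0.45). Its median was -2.91 (camera adjusted p = 6.51e-07 preset and 0.375 estimated). For xylem 5 of 7 members fell (6 adjusted over the list alone), with XCP2 at -2.9 (SE 0.34). Their median was -1.24 (camera adjusted p = 6.25e-06 preset and 0.17 estimated). All 24 measured photosynthesis genes rose, with LHCB2.1 at 6.65 (SE 0.95) and LHCB6 at 4.84 (SE 0.82) (median 5.36, camera adjusted p = 2.67e-07 preset and 0.387 estimated). The largest decreases were AT5G19110 at -6.14 (SE 0.41), CML39 (AT1G76640), a calmodulin-like protein, at -5.49 (SE 0.29) and AT5G46900 at -5.44 (SE 0.66), and AT4G06477 stood at 12.08 (SE 1.86). Of 9751 genes 4080 were called, 3068 higher, with a median of 0.361. Calls were higher in 75.2% of cases, 53.3% after median-ratio scaling and 54.2% after quantile normalization. With the shoot marker covariate 763 were called.

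At 24 h after Fo47, the jasmonate, heat shock and pattern-triggered immunity lists ranked below other genes and the nitrogen, cell cycle and ribosomal lists above them. JAZ7, a jasmonate repressor, fell from 323 ± 21.6 FPKM (SD, n = 3) to 18.3 ± 17.3 (SD, n = 3), -4.43 (SE 0.41, adjusted p = 1.39e-06), and PEPR1, a receptor of defence peptides, from 263 ± 4.52 FPKM (SD, n = 3) to 47.2 ± 12.8 (SD, n = 3), -2.49 (SE 0.28, adjusted p = 3.28e-06). NPF7.3 rose to 541 ± 160 FPKM (SD, n = 3), 2.9 (SE 0.32, adjusted p = 3.51e-06). TSO2, a ribonucleotide reductase subunit, changed by 1.68 (SE 0.21, adjusted p = 1.23e-05). In the jasmonate list 15 of 16 members fell (15 adjusted over the list alone), with AOS at -2.65 (SE 0.34). Its median was -2.58 (camera adjusted p = 6.59e-18 preset and 0.0589 estimated). For pattern-triggered immunity 1 of 17 members rose and 11 fell (1 and 11 adjusted over the list alone, median -0.733, camera adjusted p = 1.33e-08 preset and 0.122 estimated), with WRKY33 at -2.23 (SE 0.48), and for salicylic acid 1 of 13 members rose and 7 fell (1 and 10 adjusted over the list alone, median -1.21, camera adjusted p = 1.27e-07 preset and 0.0589 estimated), with the glutaredoxin GRXC9 at -2.54 (SE 0.25). In the heat shock list 12 of 14 members fell (12 adjusted over the list alone), with HSP101 at -6.56 (SE 1.12) and HSP90.1 at -5.24 (SE 0.96). Its median was -3.73 (camera adjusted p = 9.05e-10 preset and 0.258 estimated). Of the oxidative stress genes 1 of 18 members rose and 5 fell (1 and 5 adjusted over the list alone) (scaled 9 and 8), with the transcription factor RRTF1 at -3.31 (SE 0.38). Their median was -0.221 (camera adjusted p = 0.00043 preset and 0.122 estimated). In the nitrogen list 13 of 17 members rose (13 adjusted over the list alone) (scaled 6 and 8). Its median was 1.05 (camera adjusted p = 0.0073 preset and 0.258 estimated). In the cell cycle list 16 of 21 members rose (16 adjusted over the list alone, median 0.87, camera adjusted p = 0.0174 preset and 0.659 estimated) (scaled 8 and 9), and of the ribosomal proteins 6 of 6 members rose (6 adjusted over the list alone, median 1.31, camera adjusted p = 0.0054 preset and 0.341 estimated). For abscisic acid 4 of 13 members rose and 5 fell (4 and 5 adjusted over the list alone), with RD29A, a desiccation gene, at -3.2 (SE 0.45). Their median was -0.182 (camera adjusted p = 0.00964 preset and 0.306 estimated). For evening clock genes 1 of 7 members rose and 2 fell (0 and 1 adjusted over the list alone). Their median was -0.351 (camera adjusted p = 0.0219 preset and 0.464 estimated). HISN5B, of histidine synthesis, was among the largest increases, from 11.4 ± 1.88 FPKM (SD, n = 3) to 1960 ± 157 (SD, n = 3), 7.31 (SE 0.15), and AT3G44870 decreased, -5.71 (SE 0.27). The shoot marker index lay between -1.06 and 1.85. Of 12296 genes 6638 were called, 5475 higher, with a median of 0.549. Of these calls, 82.5% were higher, 51.8% after median-ratio scaling and 55.3% after quantile normalization.

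At 48 h after Fo47, almost the whole jasmonate list was low, the lists for pattern-triggered immunity, abscisic acid and oxidative stress ranked below other genes, and the iron deficiency and cell cycle lists above them. AOS changed by -2.25 (SE 0.31, adjusted p = 0.000132). BHLH39 rose to 32.5 ± 8.59 FPKM (SD, n = 3), 3.94 (SE 0.4, adjusted p = 7.79e-06). CYCD3;1, a cyclin of the G1 phase, changed by 1.84 (SE 0.2, adjusted p = 1.66e-05). In the jasmonate list 17 of 18 members fell (17 adjusted over the list alone). Its median was -1.74 (camera adjusted p = 6.99e-25 preset and 0.0149 estimated). In the salicylic acid list 4 of 16 members fell (2 adjusted over the list alone, median -0.357, camera adjusted p = 3.82e-08 preset and 0.0305 estimated), with DLO1 at -2.04 (SE 0.33), and in the oxidative stress list 1 of 18 members rose and 6 fell (1 and 6 adjusted over the list alone, median -0.473, camera adjusted p = 7.36e-07 preset and 0.0305 estimated). For pattern-triggered immunity 1 of 21 members rose and 10 fell (1 and 10 adjusted over the list alone). Their median was -0.713 (camera adjusted p = 3.51e-14 preset and 0.0589 estimated). For abscisic acid 2 of 11 members rose and 5 fell (3 and 5 adjusted over the list alone), with RD29A at -2.8 (SE 0.41). Their median was -0.0648 (camera adjusted p = 0.0011 preset and 0.255 estimated). In the iron deficiency list 13 of 18 members rose (13 adjusted over the list alone) (scaled 10 and 8). Its median was 1.73 (camera adjusted p = 0.0275 preset and 0.558 estimated). In the cell cycle list 18 of 21 members rose (19 adjusted over the list alone) (scaled 7 and 4), with CYCD3;3 at 1.48 (SE 0.18). Its median was 0.994 (camera adjusted p = 0.00741 preset and 0.571 estimated). The largest changes included CYP705A32, a cytochrome P450, at 6.75 (SE 0.27), AT3G22250 at -3.71 (SE 0.27), AT2G41640 at -3.58 (SE 0.26) and AT1G32910 at -3.39 (SE 0.38). The shoot marker index lay between -1.9 and 1.79. Of 13316 genes 6866 were called, 6122 higher, with a median of 0.586. Calls were higher in 89.2% of cases, 61.1% after median-ratio scaling and 55.7% after quantile normalization, and single libraries moved the count to 4385 without water replicate 1, 4569 without Fo47 48 h replicate 2 and 4389 without Fo47 48 h replicate 3. With the shoot marker covariate 3687 were called.

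At 96 h after Fo47, few genes still differed from water. CYP71A13, which acts in camalexin synthesis, rose from 0.517 ± 0.262 FPKM (SD, n = 3) to 29.4 ± 19.2 (SD, n = 3), 4.12 (SE 0.54, adjusted p = 0.000442), and AT2G41640 fell to 9.5 ± 0.576 FPKM (SD, n = 3), -3.61 (SE 0.26, adjusted p = 2.08e-07). The pseudogene AT3G42806 changed by 4.34 (SE 0.22, adjusted p = 3.42e-10). For tryptophan and camalexin synthesis 4 of 13 members rose (5 adjusted over the list alone) (scaled 3 and 2). Their median was 0.465 (camera adjusted p = 0.0187 preset and 0.801 estimated). As lists, iron deficiency genes stood higher (median 0.936, camera adjusted p = 0.0395 preset and 0.801 estimated), with 2 of 13 members higher adjusted over the list alone. Heat shock genes stood lower as a list (median -0.866, camera adjusted p = 0.00187 preset and 0.801 estimated). NRT2.1 was at 181 ± 90.9 (SD, n = 3) and not called. The shoot marker index lay between -2.16 and -1.87, near that of water. Of 10816 genes 272 were called, 254 higher, with a median of 0.191. Of these calls, 93.4% were higher, 84.9% after median-ratio scaling and 81.5% after quantile normalization, and single libraries moved the count to 47 without water replicate 1, 122 without water replicate 2, 59 without water replicate 3 and 90 without Fo47 96 h replicate 2.

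**Figure D3:**
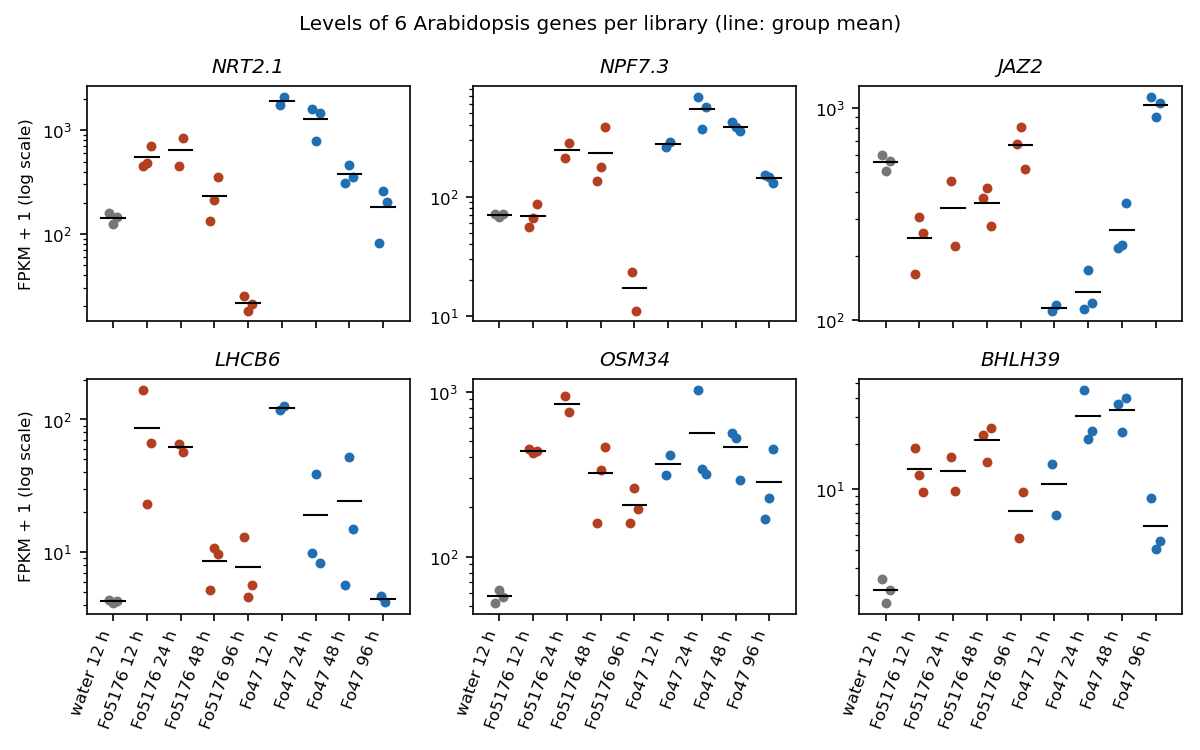
FPKM + 1 on a log axis for NRT2.1, NPF7.3, JAZ2, LHCB6, OSM34 and BHLH39 in water and in Fo5176 and Fo47 roots at each hour, with 1 point per library and a line at the group mean. NRT2.1 averages 142 FPKM in water, 20.5 with Fo5176 at 96 h and 1930 with Fo47 at 12 h.

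Genes that moved with both strains were counted next. At 12 h 2042 genes were higher and 597 lower with both, 2639 in all, where independent lists of these sizes would share 966 and 90.7, and 2 genes went opposite ways. At 24 h the 2 lists shared 1879 higher and 386 lower genes (1030 and 70.1 if independent) and 23 went opposite ways, at 48 h 1606 and 165 (813 and 11.1), and at 96 h 107 and 9 (11.8 and 0.316), with 0 opposite at both. Part of the shared increases goes with the common offset against water. After median-ratio scaling, a check chosen after seeing the data, both strains shared 1151, 770, 425 and 70 higher genes (333, 224, 77.3 and 4.53 if independent) and 959, 824, 293 and 13 lower genes (245, 230, 32.5 and 0.825). Across genes, which are not independent replicates, the fold changes of the strains correlated at 0.85, 0.761, 0.776 and 0.58. Unchanged groups simulated against the same water libraries gave 0.44, 0.443, 0.499 and 0.489. They shared 0 calls, but they held no changed genes, so this cannot show how many shared calls common water libraries add. The covariance was 1, 0.735, 0.291 and 0.143 against simulated values of 0.0507, 0.0469, 0.048 and 0.0456. The 3 water libraries cannot be split into parts of 2, so part of the excess may come from the shared controls.

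Between the strains at 12 h, the immunity, jasmonate and oxidative stress lists ranked above other genes with Fo5176 and the nitrogen list below them at the preset correlation, and few members were called. GSTF7, a glutathione transferase, stood at 2880 ± 93.7 FPKM (SD, n = 3) with Fo5176 and 1130 ± 277 (SD, n = 2) with Fo47, 1.37 (SE 0.22, adjusted p = 0.00564), and NPF7.3 differed by -2 (SE 0.35, adjusted p = 0.0103). In the oxidative stress list 4 of 16 members rose (8 adjusted over the list alone) (scaled 2 and 3). Its median was 0.835 (camera adjusted p = 1.05e-05 preset and 0.12 estimated). For pattern-triggered immunity 6 of 21 members rose (8 adjusted over the list alone) (scaled 3 and 4). Their median was 0.928 (camera adjusted p = 1.42e-05 preset and 0.313 estimated). Of the jasmonate genes 2 of 12 members rose (7 adjusted over the list alone, median 1.07, camera adjusted p = 5.97e-05 preset and 0.305 estimated) (scaled 0 and 1) and in tryptophan and camalexin synthesis 3 of 15 members rose (6 adjusted over the list alone, median 0.536, camera adjusted p = 6.77e-05 preset and 0.305 estimated). In the nitrogen list 4 of 17 members fell (5 adjusted over the list alone). Its median was -0.69 (camera adjusted p = 7.61e-05 preset and 0.159 estimated). Shoot markers did not separate the strains in the camera test, with an index of 1.03 to 4.22 and of 2.85 to 3.06. In all, 377 of 8594 genes were called, 229 higher with Fo5176, but without Fo47 12 h replicate 2 the number was 7, and limma on the compared groups alone called 0, with 974 genes at an unadjusted p under 0.05. Without that library GSTF7 differed by 1.12 (adjusted p = 0.149) and NPF7.3 by -2.07 (adjusted p = 0.149), and the genes with the largest differences, among them CYP71B22 at 2.24 (adjusted p = 0.296) and HRGP1, a wall glycoprotein, at -2.53 (adjusted p = 0.213), were not called either.

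At 24 h many jasmonate, immunity and oxidative stress genes were higher with Fo5176 than with Fo47. RRTF1 stood at 450 ± 112 FPKM (SD, n = 2) with Fo5176, 30.2 ± 14 (SD, n = 3) with Fo47 and 288 ± 29.5 (SD, n = 3) in water, 3.93 (SE 0.42, adjusted p = 2.17e-05) between the strains. DDF1, a transcription factor of the dehydration family, differed by 4.28 (SE 0.46, adjusted p = 2.17e-05) and PHI-1, a phosphate-induced wall protein, by 4.09 (SE 0.56, adjusted p = 0.000175). The auxin-responsive AT4G31320 was lower with Fo5176, -2.51 (SE 0.32). Of the jasmonate genes 11 of 16 members rose (13 adjusted over the list alone), with JAZ7 at 3.74 (SE 0.46) and CYP94B3, which inactivates jasmonoyl-isoleucine, at 3.64 (SE 0.49). Their median was 1.42 (camera adjusted p = 7.75e-13 preset and 0.0971 estimated). For pattern-triggered immunity 7 of 11 members rose (7 and 1 adjusted over the list alone), with PEPR2 at 2.26 (SE 0.36) and PEPR1 at 1.96 (SE 0.31). Their median was 1.58 (camera adjusted p = 4.51e-06 preset and 0.261 estimated). In the oxidative stress list 7 of 15 members rose (8 adjusted over the list alone). Its median was 0.703 (camera adjusted p = 9.02e-08 preset and 0.0128 estimated). For salicylic acid 3 of 12 members rose (3 adjusted over the list alone), with GRXC9 at 3.2 (SE 0.28). Their median was 0.281 (camera adjusted p = 0.00712 preset and 0.336 estimated). Iron deficiency genes stood lower as a list, with 6 of 10 members lower adjusted over the list alone (median -1.23, camera adjusted p = 0.00771 preset and 0.261 estimated). Photosynthesis genes stood higher with Fo5176 as a list (median 2.2, camera adjusted p = 2.63e-07 preset and 0.427 estimated), and the shoot marker index was 2.31 to 2.49 against -1.06 to 1.85. Of 7458 genes 780 were called, 439 higher with Fo5176, and 371 without Fo5176 24 h replicate 2, 503 without Fo47 24 h replicate 3 and 471 without Fo47 24 h replicate 2.

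At 48 h the same lists ranked above other genes with Fo5176 at the preset correlation, with few single genes called. JOX3, a jasmonate oxygenase, differed by 2.76 (SE 0.38, adjusted p = 0.00355), PROPEP1, the precursor of a defence peptide, by 1.39 (SE 0.19, adjusted p = 0.018), and AT2G26370, with 138 ± 93.2 FPKM (SD, n = 3) against 8.69 ± 2.52 (SD, n = 3), by 3.63 (SE 0.45, adjusted p = 0.0021). Of the jasmonate genes 2 of 17 members rose (14 adjusted over the list alone, median 1.33, camera adjusted p = 4.51e-19 preset and 0.0544 estimated) and for pattern-triggered immunity 1 of 20 members rose (10 adjusted over the list alone, median 0.77, camera adjusted p = 5.87e-13 preset and 0.154 estimated) (scaled 3 and 5). For oxidative stress 1 of 17 members rose and 1 fell (4 and 1 adjusted over the list alone) (scaled 2 and 1). Their median was 0.295 (camera adjusted p = 0.00121 preset and 0.162 estimated). Abscisic acid genes stood higher as a list, with 6 of 11 members higher and 1 lower adjusted over the list alone (median 0.711, camera adjusted p = 0.000286 preset and 0.198 estimated). Of 12455 genes 102 were called, 79 higher with Fo5176, but 18 in a fit on the compared groups alone, 52 with the shoot marker covariate, and 7 without Fo5176 48 h replicate 1, 67 without Fo5176 48 h replicate 2, 156 without Fo47 48 h replicate 1, 31 without Fo47 48 h replicate 2 and 11 without Fo47 48 h replicate 3.

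At 96 h, the nitrogen and suberin lists ranked below other genes with Fo5176 compared with Fo47 and the sugar transport list above them, of which only nitrogen held with an estimated correlation. NRT2.1 differed by -2.94 (SE 0.39, adjusted p = 0.000263), with 20.5 ± 3.56 FPKM (SD, n = 3) against 181 ± 90.9 (SD, n = 3), and NPF7.3 by -3.14 (SE 0.35, adjusted p = 4.85e-05). The nitrate reductase NIA1 differed by -1.37 (SE 0.21, adjusted p = 0.00156). TAT3 was higher with Fo5176, 2.28 (SE 0.36, adjusted p = 0.00174), and so was AT2G16005, a lipid-recognition protein, at 944 ± 454 FPKM (SD, n = 3) against 21.4 ± 10.6 (SD, n = 3), 5.39 (SE 0.53, adjusted p = 2.06e-05). Of the nitrogen genes 6 of 15 members fell (8 adjusted over the list alone). Their median was -0.633 (camera adjusted p = 3.65e-07 preset and 0.0199 estimated). In the suberin list 4 of 16 members fell (6 adjusted over the list alone), with KCS2, which elongates suberin acids, at -1.53 (SE 0.21). Its median was -0.496 (camera adjusted p = 2.86e-05 preset and 0.314 estimated). For phenylpropanoids 2 of 12 members fell (1 and 5 adjusted over the list alone) (scaled 2 and 1), with LAC11 at -1.29 (SE 0.23). Their median was -0.518 (camera adjusted p = 0.00269 preset and 0.384 estimated). In the sugar transport list 1 of 5 members rose (3 adjusted over the list alone) (scaled 1 and 0), the member being STP13, a hexose transporter, at 1.48 (SE 0.31), whose adjusted p was 0.0573 without Fo5176 96 h replicate 1, 0.0689 without Fo5176 96 h replicate 3 and 0.0565 without Fo47 96 h replicate 2. Its median was 0.841 (camera adjusted p = 0.00217 preset and 0.314 estimated). In the senescence list 1 of 2 members rose (1 adjusted over the list alone). Its median was 1.09 (camera adjusted p = 0.0308 preset and 0.314 estimated). The defensin PDF2.1 was lower with Fo5176, -2.34 (SE 0.34), and scpl30 higher, 5.53 (SE 1.03). The shoot marker index was -1.58 to 0.142 against -2.16 to -1.87, and photosynthesis genes stood higher with Fo5176 as a list (median 0.998, camera adjusted p = 0.0297 preset and 0.728 estimated). Of 10094 genes 268 were called, 143 higher with Fo5176, but 95 in a fit on the compared groups alone, and 121 without Fo5176 96 h replicate 1, 167 without Fo5176 96 h replicate 2, 152 without Fo5176 96 h replicate 3 and 148 without Fo47 96 h replicate 3.

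Over the mean of the 4 hours, the jasmonate, immunity and oxidative stress lists ranked above other genes with Fo5176 and the nitrogen and ribosomal lists below them, of which only oxidative stress kept its call at an estimated correlation. JOX3 differed by 1.77 (SE 0.2, adjusted p = 1.55e-05), PEPR2 by 1.19 (SE 0.17, adjusted p = 0.00012), RRTF1 by 1.82 (SE 0.2, adjusted p = 1.08e-05) and NRT2.1 by -1.63 (SE 0.21, adjusted p = 3.19e-05). AT2G26370 at 2.62 (SE 0.25), AT4G37710, a VQ-motif protein, at 2.16 (SE 0.19) and NPF7.3 at -1.78 (SE 0.17) showed the largest differences with the same sign at all 4 hours. Of the jasmonate genes 9 of 11 members rose (10 adjusted over the list alone, median 0.82, camera adjusted p = 1.66e-08 preset and 0.0907 estimated), and for pattern-triggered immunity 8 of 11 members rose (8 adjusted over the list alone, median 0.866, camera adjusted p = 1.85e-06 preset and 0.252 estimated). In the oxidative stress list 8 of 14 members rose (9 adjusted over the list alone). Its median was 0.539 (camera adjusted p = 6.67e-07 preset and 0.0337 estimated). In the ethylene list 5 of 13 members rose and 1 fell (5 and 1 adjusted over the list alone), with ERF1B at 0.82 (SE 0.16). Its median was 0.23 (camera adjusted p = 0.0072 preset and 0.458 estimated). Of the nitrogen genes 1 of 15 members rose and 10 fell (1 and 11 adjusted over the list alone, median -0.517, camera adjusted p = 0.000346 preset and 0.0907 estimated), with 7 lower after median-ratio scaling, and of the ribosomal proteins 5 of 6 members fell (6 adjusted over the list alone, median -0.351, camera adjusted p = 0.0414 preset and 0.542 estimated) (scaled 3 and 6). Of 5705 genes 1667 were called, 675 higher with Fo5176, whereas of the 188 that differed by 2-fold 159 were higher. A change of the strain difference with time was called for 134 of those genes, among them GSTF7, DDF1 and JAZ2. Splits of the libraries did not exclude chance for this count, as the closing section states. It also depended on single libraries. The count was 214 without Fo5176 12 h replicate 1, and 68, 68 and 67 without Fo5176 96 h replicates 1, 2 and 3. Without Fo47 24 h replicates 3 and 2 it was 65 and 51, and without Fo47 48 h replicate 2 it was 88. Without Fo47 96 h replicates 1 and 3 it was 440 and 71. A fit on the inoculated groups alone gave 63.

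**Figure D4:**
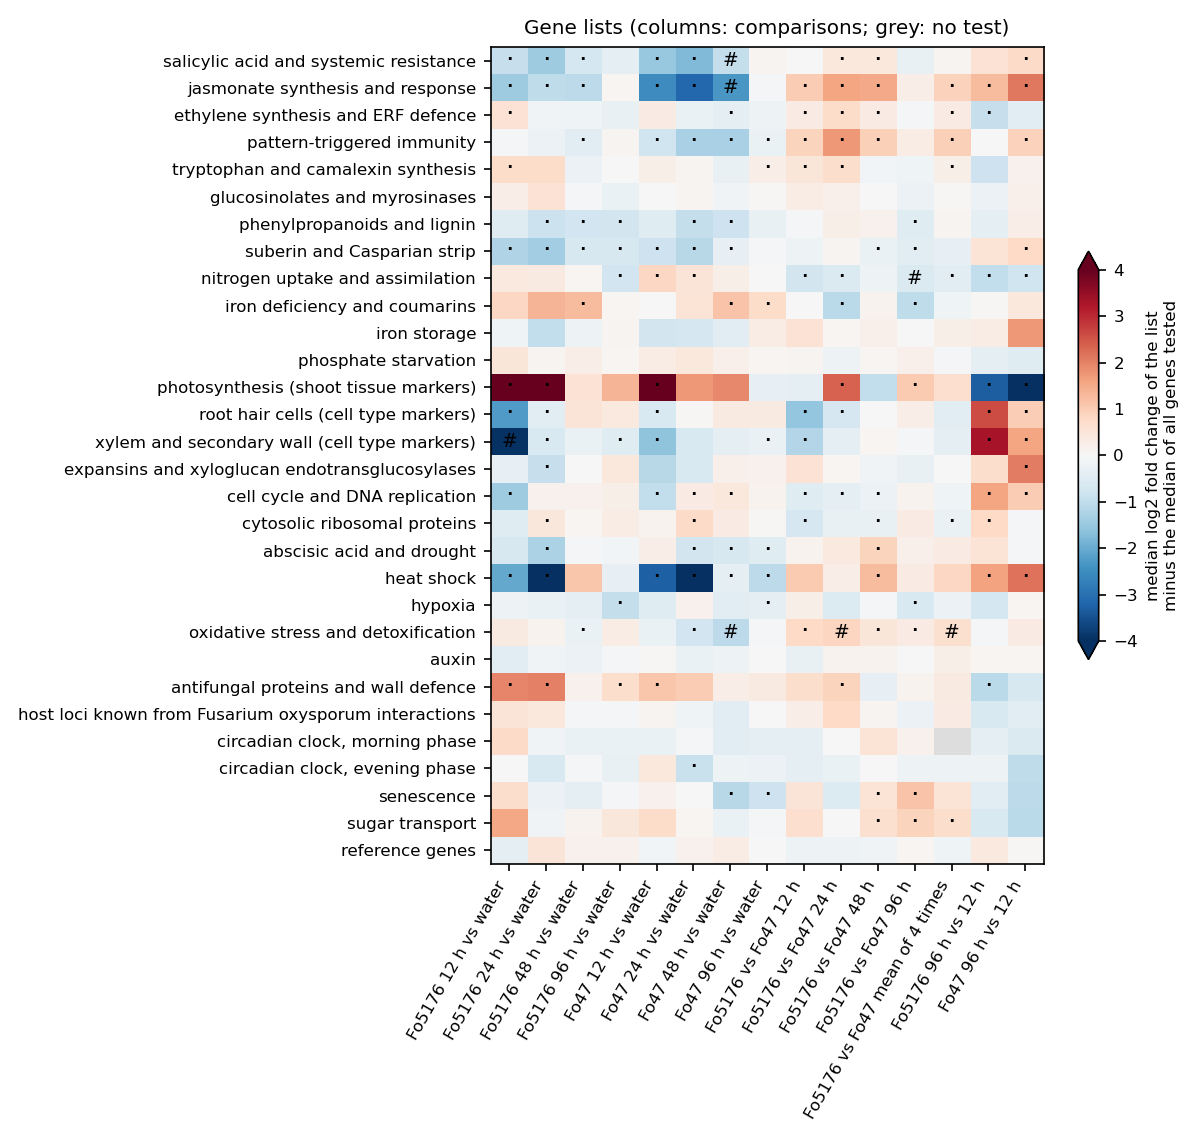
Median log2 fold change of each gene list minus that of all tested genes, by comparison, as a colour scale. A dot marks an adjusted p below 0.05 from camera at the preset correlation, # marks a call that also holds with an estimated correlation, and grey means no test. Jasmonate genes are below all genes for both strains at 12 h and 24 h, with list medians of -1.03 and -0.612 for Fo5176 and -2.16 and -2.58 for Fo47.

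Within a strain, 96 h was set against 12 h, both inoculated and listed alike. With Fo5176, XCP2 rose by 3.44 (SE 0.31, adjusted p = 1.58e-07) and KN by 2.53 (SE 0.31, adjusted p = 5.46e-06), and NRT2.1 fell, -4.66 (SE 0.39, adjusted p = 8.25e-08). In the photosynthesis list 18 of 19 members fell (18 adjusted over the list alone). Its median was -3.53 (camera adjusted p = 0.000339 preset and 0.605 estimated). For root hairs 5 of 6 members rose (6 adjusted over the list alone, median 2.39, camera adjusted p = 7.89e-05 preset and 0.282 estimated), for xylem 2 of 2 members rose (2 adjusted over the list alone, median 3.06, camera adjusted p = 0.000847 preset and 0.159 estimated), for the cell cycle 8 of 11 members rose (9 adjusted over the list alone, median 1.35, camera adjusted p = 4.2e-06 preset and 0.282 estimated) and for jasmonate 9 of 18 members rose (10 adjusted over the list alone, median 1.04, camera adjusted p = 2.8e-06 preset and 0.282 estimated). Of the nitrogen genes 10 of 16 members fell (11 adjusted over the list alone, median -1.22, camera adjusted p = 0.000692 preset and 0.282 estimated), in the ethylene list 13 of 19 members fell (1 and 13 adjusted over the list alone, median -1.17, camera adjusted p = 0.00341 preset and 0.464 estimated) and in the antifungal list 8 of 10 members fell (1 and 8 adjusted over the list alone, median -1.32, camera adjusted p = 0.0458 preset and 0.475 estimated). With Fo47, JAZ2 changed by 3.17 (SE 0.3, adjusted p = 8.19e-07) and NRT2.1 by -3.56 (SE 0.44, adjusted p = 1.17e-05). In its jasmonate list 10 of 12 members rose and 1 fell (11 and 1 adjusted over the list alone, median 1.99, camera adjusted p = 3.09e-06 preset and 0.24 estimated), in its nitrogen list 8 of 15 members fell (9 adjusted over the list alone, median -0.935, camera adjusted p = 0.000486 preset and 0.24 estimated), and in its photosynthesis list 9 of 9 members fell (9 adjusted over the list alone, median -4.93, camera adjusted p = 0.00018 preset and 0.499 estimated). For expansins and their partners 4 of 7 members rose and 1 fell (4 and 1 adjusted over the list alone). Their median was 1.9 (camera adjusted p = 0.0235 preset and 0.24 estimated). In all 3785 of 9687 genes were called with Fo5176, 1290 higher at 96 h, and 2531 of 8151 with Fo47, 1067 higher. The Fo47 number was 1677 without Fo47 12 h replicate 2. In fits on the compared groups alone the numbers were 1960 and 1218, and with the shoot marker covariate 1628 and 587.

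Some lists were not called by camera in any comparison, although single members passed the test. Of glucosinolate and myrosinase genes, 10 of 15 were higher with Fo5176 at 24 h (10 adjusted over the list alone, adjusted p = 0.0862), but 4 and 3 after the 2 rescalings. Of phosphate starvation genes, 7 of 10 were higher with Fo47 at 24 h (8 adjusted over the list alone, adjusted p = 0.215), but 2 after each rescaling. Of auxin genes, 3 of 19 were higher and 4 lower with Fo5176 at 12 h (3 and 4 adjusted over the list alone, adjusted p = 0.0553). Of 2 measured iron storage genes 1 was lower with Fo47 at 12 h (1 adjusted over the list alone, adjusted p = 0.37). Of host loci known from Fusarium interactions, 5 of 8 were lower and 1 higher at 96 h than at 12 h with Fo5176 (5 and 1 adjusted over the list alone, adjusted p = 0.303). Of morning clock genes, 1 of 4 was higher with Fo47 at 48 h (1 adjusted over the list alone, adjusted p = 0.298), which was CCA1, 2.83 (SE 0.75, adjusted p = 0.0171), with an adjusted p of 0.0551 after median-ratio scaling and 0.0809 after quantile normalization. Of reference genes, 2 of 3 were higher with Fo47 at 48 h, and 3 adjusted over the list alone (adjusted p = 0.274), but 1 after each rescaling. Among genes fixed for naming, FRK1 rose with Fo5176 at 12 h, 2.5 (SE 0.34, adjusted p = 0.000213), CYP71B15 rose with both strains at 24 h, with Fo47 by 2.64 (SE 0.29, adjusted p = 9.61e-06), MYB51, a regulator of indole glucosinolates, was lower with Fo47 at 24 h, -1.31 (SE 0.4, adjusted p = 0.0113), TOC1 was lower with Fo47 at 24 h, -1.09 (SE 0.31, adjusted p = 0.0115), and LHCB1.1 was higher with Fo5176 at 24 h, 5.27 (SE 1.08, adjusted p = 0.00307). PR1 was listed at 0 in all 3 water libraries and PDF1.2A in 2 of them, whereas JAZ10 averaged 468 ± 28.4 FPKM (SD, n = 3) in water, FER1 37.7 ± 8.73 (SD, n = 3) and RFO1 13.9 ± 3.1 (SD, n = 3).

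Fungal genes in roots were compared with mycelium in culture. In Fo5176, FOXB_18620 rose from 0 and 37.3 FPKM in the culture libraries to 4170 ± 1820 (SD, n = 3) at 12 h and 91200 ± 43100 (SD, n = 3) at 48 h, 9.29 (SE 1.45, adjusted p = 0.000849) and 13.70 (SE 1.45, adjusted p = 4.41e-05). FOXB_08691 was listed at 0 in both culture libraries and stood at 16000 ± 3380 (SD, n = 3) at 12 h and 17000 ± 10000 (SD, n = 3) at 96 h, but at 6350 ± 11000 (SD, n = 3) at 48 h, where it was not called (adjusted p = 0.286). FOXB_08585 went the other way, from 197000 and 212000 FPKM in culture to 0 in every root library, and FOXB_17530 from 29700 and 92200 FPKM to 0 in all 6 libraries at 48 h and 96 h. In Fo47, FOZG_00156 rose from 0.388 ± 0.195 (SD, n = 2) to 54100 ± 14800 (SD, n = 3) at 24 h, 15.22 (SE 0.4, adjusted p = 9.15e-09), and FOZG_16550 by 12.51 (SE 0.8, adjusted p = 9.52e-07) at 24 h. FOZG_10699 stood at 8230 and 10900 FPKM in culture and was listed at 0 in all root libraries, and FOZG_10762 at 29300 and 31100 FPKM in culture at 0 in the 3 libraries at 48 h (adjusted p = 0.00862, but 0.0639 or 0.06 without culture library a or b), and at 14600, 18000 and 16000 FPKM on average at 12, 24 and 96 h, where it was not called. The files pair no fungal gene with a product. Of 15267 Fo5176 genes, 4111, 3910, 6200 and 4605 differed from culture at 12, 24, 48 and 96 h, of which 1718, 1376, 1078 and 1068 were higher in roots. Of 13300 Fo47 genes, the numbers were 2257, 2959, 3450 and 3404, of which 944, 1407, 861 and 738 were higher. From 12 h to 96 h, 2567 Fo5176 genes and 1914 Fo47 genes changed in roots, of which 618 and 379 were higher at 96 h. These numbers rested on the 2 culture libraries of a strain. Without culture library a or b, the Fo5176 number was 1527 or 1275 at 12 h, 1460 or 1165 at 24 h, 3233 or 2466 at 48 h and 2010 or 1390 at 96 h, and the Fo47 number 599 or 534, 938 or 845, 1058 or 1140, and 907 or 981. The Fo5176 number at 24 h was also 2605 without Fo5176 24 h replicate 2 and 2545 without replicate 3. From 12 h to 96 h the Fo5176 number was 1608 without Fo5176 12 h replicate 1, and the Fo47 number was 849 or 1175 without Fo47 12 h replicate 2 or 3.

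The mean number of fungal genes with at least 1 FPKM was lowest at 48 h in both strains, but at 10 FPKM the Fo47 mean was 5768 at 48 h and 4826 at 96 h. At 1 FPKM, genes numbered 12441 ± 59 (SD, n = 3) for Fo5176 at 12 h, 7511 ± 1857 (SD, n = 3) at 48 h, 10463 ± 611 (SD, n = 3) at 96 h and 12612 ± 450 (SD, n = 2) in culture. For Fo47 they numbered 10366 ± 131 (SD, n = 2) at 12 h, 10834 ± 203 (SD, n = 3) at 24 h, 6694 ± 598 (SD, n = 3) at 48 h, 7229 ± 150 (SD, n = 3) at 96 h and 10616 ± 503 (SD, n = 2) in culture. In exact two-sided permutation tests of 3 against 3 libraries, p was 0.1, the smallest the design allows, with an adjusted p of 0.12, except for Fo47 at 48 h against 96 h with p = 0.2. Depth fell at the same hours, though detection did not follow it throughout. For Fo47 at 24 h, with more genes than at 12 h, 1 fragment was worth 14.8 to 46.2 times that in culture replicate b. The depth of Fo5176 48 h replicate 1 rested on 23 low genes. The worth of 1 fragment, relative to culture replicate b, was 2.16 to 2.91 for Fo5176 at 12 h, 29.0 to 104 at 48 h and 5.5 to 22.3 at 96 h, and 8.28 to 18.6, 127 to 410 and 63.6 to 153 for Fo47. Genes of low level were therefore not detectable at 48 h in these libraries, which does not show that they were absent.

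**Figure D5:**
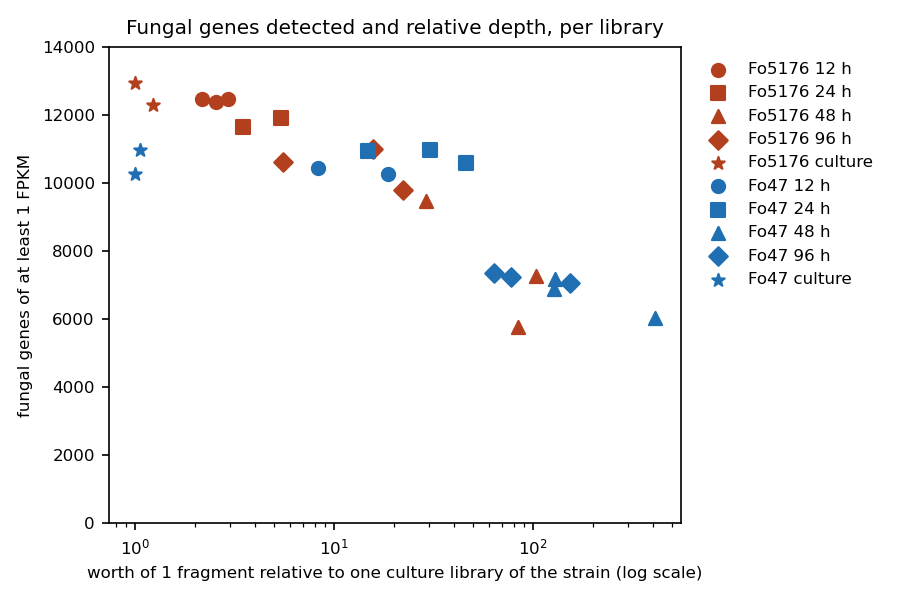
Number of fungal genes with at least 1 FPKM per library against the worth of 1 fragment relative to 1 culture library of the strain, on a log axis, so that depth falls to the right. Libraries at 48 h lie at 29.0 to 104 for Fo5176 and 127 to 410 for Fo47, with means of 7511 and 6694 genes.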

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

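Of the tests in this part, those on quantification, time of day, low values and root share were chosen only after the result was seen. The test of whether the strain difference changed with time called 134 genes, and 17 of the named genes were among them. For the glutathione transferases GSTF7 and GSTF2 the adjusted p was 0.000342 and 0.000428, and GSTF7 stood at 2880 ± 93.7 (SD, n = 3) FPKM with Fo5176 against 1130 ± 277 (SD, n = 2) with Fo47 at 12 h but 509 ± 47.2 (SD, n = 3) against 1030 ± 86.7 (SD, n = 3) at 48 h. It was 0.00146 for DDF1, 0.00388 for RRTF1, 0.00314 for GRXC9 and 0.0224 for PEPR1, whose difference was large at 24 h. Indole pathway enzymes gave 0.00617 (CYP71A12), 0.0252 (CYP71A13) and 0.0363 (CYP71B6), and jasmonate genes 0.0359 (JAZ2) and 0.0333 (JOX3). AT2G16005 had 0.00294, AT2G26370 0.0218, NPF7.3 0.0398 and NAP, a senescence factor, 0.0365, and the last 2 were AT3G28550 at 0.0399 and GLIP1 at 0.0427. Of 100 splits of the inoculated libraries 5, the real one included, gave at least 134 genes and the highest 800, so chance is not excluded. A split with several times the real count points to some structure of the samples, and what it is was not tested.

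For the strain difference over the mean, 1 of 100 splits, the real one, gave 1667 genes, and the highest other gave 607. This argues against chance without excluding it, as only 100 splits were drawn. For 3 libraries against 3 the splits are too few. There the real value and the highest other were 4822 and 35 for Fo5176 at 12 h against water, 2081 and 0 at 48 h, 1017 and 1 at 96 h, 6638 and 190 for Fo47 at 24 h, 6866 and 0 at 48 h, 272 and 0 at 96 h, 102 and 1 between strains at 48 h, 268 and 46 at 96 h, 3785 and 79 for Fo5176 96 h against 12 h, and 2567 and 12 for Fo5176 fungal genes 96 h against 12 h.

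Photosynthesis genes were higher at 12 h than at 96 h, by a median of 3.67 on the log2 scale in Fo5176 roots with unlisted loci at 0. The different listing of water is argued against, since 2 inoculated groups differed by -3.53 (96 h against 12 h). Time of day is argued against as well, since 24 h and 96 h fell at the same hour and differed by 3.35. Shoot tissue in the samples may be a source, because 14 leaf epidermis and polarity genes were higher at 12 h than at 96 h by 0.763 more than all genes, 11 of them higher, such as LTP1 at 90.4 against 9.37 FPKM, while PDF1 was lower at 29 against 63.7. The median of 0.862 had a 95% interval of 0.335 to 1.79, and the difference lies between the bounds set for and against it, so shoot tissue cannot be told apart from light-driven expression in the root, which stays untested.

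Most calls against water were higher in inoculated roots. Low values left out of the inoculated listing are argued against as the whole cause, since among loci of at least 20 FPKM a median of 73.2% of calls was still higher. A single scale factor between water and the other libraries could account for part of it, which was not settled. Loci of 20 to 50 FPKM and of at least 200 FPKM shifted alike, with a median difference of -0.0225 over 8 comparisons, although single comparisons ranged from -0.239 to 0.167.

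The nitrogen list ranked below other genes with Fo5176 compared with Fo47 at 96 h. The Fo47 library that stood apart, replicate 1, is argued against, since without it the list median was -1.05 over 14 members. A lower share of root tissue with Fo5176 cannot be told apart from regulation by the strain. Members of the root hair, xylem and suberin lists had a median of -0.207 (95% interval -0.305 to -0.0537, 26 of 38 lower), which spans the bound set against it. A response to the strain may remain, as a hypothesis.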

How the results depend on the processing

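The alternatives that put unlisted loci at 0, used the median or lowest of several lines, kept only loci listed once in all 25 libraries or of at least 20 FPKM, added a shoot marker covariate, kept fungal genes of at least 50 FPKM, set fungal zeros as missing, or rescaled the overlap of calls were chosen after seeing the data, as was the way quantile normalization was carried to loci missing in some libraries. Of 460 values of named genes, 6588 of 6874 recomputations under other settings kept the direction and the side of the threshold, 229 lost the call, 55 gained it and 2 reversed. With 1 library left out, 3088 of 3307 kept both, 197 lost the call and 22 gained it. The reversals came with the shoot marker covariate, AT2G10735 for Fo47 at 12 h against water at -3.23 (9.18 without it) and LHCB1.1 for Fo5176 at 12 h at -0.32 (4.73 without it). LHCB1.1 is on the photosynthesis list but had values in too few libraries to be among the 16 genes of the covariate. Limits of the counts include the water group, sampled at 1 hour and listed differently, the loci missing from inoculated libraries, and the low fungal depth at 48 h and 96 h. Except where the construction shows it, the cause of a changed count was not tested. The counts did not move by over 1.5 times with a pseudocount of 0.1, other filters, no trend or the median of several lines.

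A 2-fold minimum left 2893, 1743, 895 and 662 genes for Fo5176 against water at 12, 24, 48 and 96 h, 2472, 3481 and 2564 for Fo47 at 12, 24 and 48 h, 249 between strains at 12 h and 188 over the mean, 2050 and 1512 for 96 h against 12 h in Fo5176 and Fo47, and 1502, 1102, 625 and 76 shared by both strains. Settings that test fewer genes gave fewer calls. Loci listed once in all libraries gave 1699, 1426, 502 and 373 for Fo5176 and 1560, 2314, 1831 and 56 for Fo47 against water, 504 and 112 between strains at 24 h and 96 h, 1668 and 1294 for 96 h against 12 h, and 86 for strain by time. Loci of at least 20 FPKM gave 2273, 1688, 759 and 541 for Fo5176 and 2173, 3200, 2709 and 63 for Fo47, 2341 and 1667 for 96 h against 12 h, and 204 between strains at 48 h, more than over all loci. The shoot marker covariate left 847, 603, 1319 and 663 for Fo5176, 763 and 3687 for Fo47 at 12 h and 48 h, 52 between strains at 48 h, and 1628 and 587 for 96 h against 12 h. Median-ratio scaling gave 959 for Fo5176 at 48 h and 4401, 3133 and 172 for Fo47 at 24, 48 and 96 h. Quantile normalization gave 589, 4212, 2635 and 81 for the same 4, 200 between strains at 48 h and 4054 Fo5176 fungal genes at 48 h. A fit on the compared groups alone gave 3957 and 2232 for Fo5176 at 48 h and 96 h, 519, 18 and 95 between strains at 24, 48 and 96 h, 1960 and 1218 for 96 h against 12 h, 63 for strain by time, and 7929, 7809, 5560 and 5228 fungal genes of Fo5176 and Fo47 at 12 h and 24 h. In that limma fit the strains at 12 h gave 0 calls, with 974 genes at an unadjusted p under 0.05. Array weights gave 7872 and 3964 for Fo5176 at 48 h and 96 h, 10416 for Fo47 at 48 h, 3108 between strains at 48 h, 444 for strain by time, 9116, 8114 and 8130 Fo5176 and 5256, 5804 and 5448 Fo47 fungal genes at 12, 24 and 96 h, and 4576 and 3074 for fungal 96 h against 12 h. The lowest of several lines gave 1358 for Fo5176 at 48 h, a pseudocount of 5 gave 157 for Fo47 at 96 h, and unlisted loci at 0 gave 465 there, 610 between strains at 12 h and 274 for strain by time. Fungal genes of at least 50 FPKM gave 1029, 1060, 1433, 1237 and 974 for Fo5176 at the 4 hours and 96 h against 12 h, and 742, 921, 859, 998 and 744 for Fo47. Calls shared by both strains were 718 at 48 h after median-ratio scaling and 1428, 448 and 50 at 24, 48 and 96 h after quantile normalization. With zeros as missing, 48 h gave 2776 and 1850. Fo47 genes detected at 48 h, 63.0% of culture at 1 FPKM, were 46.6% above 0 and 89.7% at 10 FPKM.

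Leaving out 1 library gave ranges of 1882 to 3356, 632 to 1881 and 489 to 744 for Fo5176 at 24, 48 and 96 h against water, 4385 to 6150 and 47 to 404 for Fo47 at 48 h and 96 h, 7 to 391, 371 to 754, 7 to 156 and 121 to 261 between strains at the 4 hours, 1677 to 2559 for Fo47 96 h against 12 h, and 51 to 440 for strain by time. For fungal genes at the 4 hours and 96 h against 12 h they were 1275 to 3418, 1165 to 2605, 2466 to 6845, 1390 to 4504 and 1608 to 2380 in Fo5176, and 534 to 1802, 845 to 2817, 1058 to 3589, 907 to 3506 and 849 to 2150 in Fo47. Where 1 library was left, it was assumed to vary like the other groups. Replicate numbers did not pair the libraries. Deviations of same-numbered root libraries correlated at -0.011 on average, with 20 of 93 pairs over 0.1 and 6 of 25 libraries closest to their own number, and no fungal pair was over 0.1. With the number as a block, calls were 171 for Fo47 at 96 h against water and 162 between strains at 12 h.

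With an estimated correlation camera called 7 list comparisons, 3 for oxidative stress and 1 each for salicylic acid, jasmonate, nitrogen and xylem, and 0 for the other lists called at the preset correlation, where 27 of their 270 tests had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 6 comparisons were called for glucosinolates and for reference genes, 5 for phosphate and sugar, 4 for immunity, suberin, expansins, heat shock and auxin, 3 for phenylpropanoids, photosynthesis, abscisic acid, host loci and evening clock, and 1 for iron storage, xylem, morning clock and senescence.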

Other observations

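No test in this part was planned; all were chosen after the data were seen. The Fo5176 table sorts its genes into divisions named Core (9695 genes), AUX (8945) and UNIQ (1551), names that are not explained in the sources used here. At 12 h in roots, 12.2% of tested AUX genes, 11.1% of Core genes and 7.6% of UNIQ genes were higher than in culture. At 48 h the shares were 4.17%, 9.37% and 3.04%. Depth was low at 48 h. The test was therefore repeated on genes with a mean of at least 50 FPKM over the Fo5176 libraries, cultures included. There 138 of 619 AUX, 430 of 1873 Core and 29 of 328 UNIQ genes were higher at 12 h, and 139, 577 and 26 at 48 h, while lower genes went from 91, 254 and 43 to 207, 336 and 117. UNIQ genes were higher less often than the rest at all 4 hours, with odds ratios of 0.329, 0.194, 0.214 and 0.222 (Fisher's exact test, adjusted p = 9.49e-10, 3.15e-16, 5.14e-18 and 4.87e-16). Core genes were higher more often, with odds ratios of 1.39, 1.41, 2.11 and 1.99 (adjusted p = 0.0016, 0.000983, 2.54e-14 and 7.74e-12). Genes are not independent, as the test assumes, so these p-values are unreliable.

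The course over the hours was followed for 2 genes low at 12 h with both strains. AT4G37710, a VQ-motif protein, averaged 178 ± 11.7 (SD, n = 3) FPKM in water. With Fo5176 it stood at 23.1 ± 5.01 (SD, n = 3) at 12 h and 515 ± 46.6 (SD, n = 3) at 96 h, and with Fo47 at 4.24 ± 0.55 (SD, n = 2) and 194 ± 91.5 (SD, n = 3). LAC11, a laccase, averaged 52.8 ± 8.24 (SD, n = 3) in water, 4.39 ± 1.03 (SD, n = 2) with Fo5176 and 5.15 ± 0.782 (SD, n = 2) with Fo47 at 12 h, and already 41.3 ± 2.41 (SD, n = 2) and 56 ± 2.92 (SD, n = 3) at 24 h.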
